A study of Saccharomyces cerevisiae with 312 samples.

How the data were processed

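The data come from genetic interaction mapping screens in budding yeast. In this method a query mutation is crossed into a pool of barcoded mutant strains, double mutants are selected and grown together, and each strain's barcode level is compared with that in a reference population. Per the labels, the pools grew for 18 generations and both barcodes of each strain were hybridised to dual-colour arrays with the query population in Cy3 and the reference in Cy5. The series holds 312 arrays of 154 query mutations, of which 139 were deletions, 11 were DAMP alleles (destabilised transcripts) and 4 were TETO2 alleles (a repressible promoter). Of 304 independent screens, 8 were hybridised on 2 arrays each, and these arrays were averaged. There were 133 queries with 2 screens, 4 with 3 and 3 with 4, and these 140 were tested. The other 14 had 1 screen and are given as values only. The labels do not state whether the screens of a query were separate cultures, so the p-values measure only the spread between these samples, pooled over queries. The reference was 1 of 31 pools: 252 arrays used a mix of many deletions in 23 pools, and 60 arrays used a single deletion strain.

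The deposited values are ratios of the 2 channels, taken here as log2 ratios, with 1 value per array feature. The log base is not stated, and base 2 was chosen because natural logarithms would make the highest value a ratio of 13526710. The normalization before deposit, its scale, its centring and the sign of the ratio are not given in the sources used here. Values ran from -14.59 to 16.42. Medians per array ran from -0.19 to 0.48 (median 0.02), and SDs from 0.403 to 1.93 (median 0.740). Signal over background cannot be read from ratios, so the number of arrays limits the precision. Each array held values for 6504 to 12804 of 15744 features (median 10846.5).

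Of the features, 13084 had 1 gene symbol, 0 had several and 2660 had none. The last were left out. Of 5100 symbols, 5098 matched the R64 annotation, and 64 were updated. The annotation served for names and gene order only, so distances are given in genes and not in kilobases. Features present on at least 80% of arrays were kept, 8632 in all. Features of a strain were averaged, which gave 4125 strains: 2483 with 2 features, 992 with 1 and 650 with more. Across arrays, the 2 features of a strain correlated with a median r of 0.744 (5th percentile 0.392, 95th percentile 0.948). An array measured 3290 to 4125 strains. Each array was centred on its median. The pool holds strains altered in essential genes as well, so a pool member is called a strain here, named by its gene.

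The direction of each array was read from linkage. Strains altered near the query locus cannot easily combine both markers in 1 spore, so they should be depleted from the query population. On 295 arrays the strains within 25 genes of the query had a negative median, from -5.24 to -0.65. On the 17 arrays of 2 reference pools (8 and 9 arrays) this median was positive, from 1.57 to 3.77. Those pools likely hold the opposite ratio, and their arrays were multiplied by -1. The basis is linkage and not a label, so most results are also given with all arrays as deposited. A negative value then means fewer cells in the query population than in the reference.

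Each strain was fitted with limma 3.58.1 in R 4.3.3, with a mean per query and moderated variances. The variance of a strain was pooled over all queries. A small p for a pair therefore does not show that the screens of that query agree, and the SD beside a value gives their spread. The same fit in closed form for all strains was checked against limma on 200 strains. The prior had 4.82 degrees of freedom beside a median of 150 residual ones, and the median residual SD was 0.382. Strains within 100 genes of a query locus were left out for that query. A strain and query pair needed at least 2 screens. The Benjamini-Hochberg correction ran over all 547925 pairs, and a call needed an adjusted p under 0.05 and a log2 size of at least 1. "Lower" and "higher" mean such calls. Query means per strain were then compared between 11 classes of 89 queries and the other queries, again with limma, at an adjusted p under 0.05 over strains and a difference of at least 0.5. Values of a strain in a query are means ± SD over screens, which number 2 unless stated. Class values are the class mean minus the mean of the other queries, and their SD is between queries. Limma tests were two-sided.

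Permutation tests used 100000 draws, so 1e-05 is the smallest p they can give. All permutation tests were two-sided. Enrichment of 30 gene lists among lower calls used one-sided Fisher exact tests, with the strains tested in that query as background. Profile correlations are Pearson's r across strains outside the linked windows, and strains are not independent replicates. Query classes, gene lists, gene pairs, query pairs, thresholds and the naming rule were fixed before the data were examined.

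The rule names, per class, at most 8 lower and 4 higher strains of smallest p. It names the class's own genes as strains. For each class query it names the 2 lowest and the highest called strains on the same side in every screen that were called in at most 10% of queries. The last part also covers the 10 queries outside the classes with most calls. All fixed pairs measured and the 10 strains called most often are named as well. From these the text gives mainly pairs in which every screen passed 1 in size. Other genes are said to be chosen after their values were seen.

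Alternatives included the reference pool as a block in the model, with MTQ2 left out because its pool served no other query. This block could be fitted for 3973 strains. With it, the value of a strain in a query is relative to the mean of the queries that shared pools connect. These connected sets held 140 and 13 queries. The main fit has no such baseline and takes each query against its reference population alone. Single values and call counts with the block therefore reflect the changed baseline as well as the pool adjustment. Others were no centring, quantile normalization, replicate number as a block, leaving out each replicate, strains present on every array (2122), other thresholds and other windows. Chosen after the data were seen were all arrays as deposited, the 17 turned arrays left out, strains linked to the reference deletion left out, and a count of calls in which every screen passed 1. The reference block was also added after the data were seen for classes against lists, list enrichment and allele type.

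The procedure was tested on simulated data with known changes among 4125 strains. The noise was drawn as normal and independent, without effects of reference pools or of the reference locus. The rates below hold for such noise and do not give the false calls of the real data. Of 200 changed pairs per size, 78.5% were recovered at -1.5, 90.0% at -2, 99.5% at -3, 81.5% at 1.5, 93.0% at 2 and 96.5% at 3, with 41 false calls among 546725 unchanged pairs. For classes compared with the other queries, differences of -1 and -2 were recovered in 99.0% and 100% of strains for the proteasome, 93.0% and 99.5% for ribosomal proteins, and 82.5% and 96.5% for OCA. Shuffled calls over the 4125 strains gave 0 enriched lists among 4109 query and list pairs, and 20 of 20 planted lists were found. The shuffle made every strain equally likely to be called, as the Fisher test assumes. It therefore does not give the false enrichments among real calls, where some strains respond often. The formula for permutation p-values, applied to random normal numbers, gave 34 of 500 p-values under 0.05. Permutation of the query labels itself was not simulated, so this does not test it on correlated screens. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.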

Results

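The series measured how 154 query mutations change the levels of other yeast mutants in a pool. The query genes act mainly in the synthesis and breakdown of RNA and protein. Each value is the level of a barcoded strain in a population carrying the query mutation relative to a reference population. A negative value is read as a double mutant that grew worse than its neighbours in the pool, and a positive value as better growth. Growth itself was not measured, and linkage or the reference pool can also move a value. The 312 arrays gave values for 4125 strains in 304 screens. Of the queries, 140 had at least 2 screens and 14 had 1. Arrays differed in how much they measured, from 3290 to 4125 strains. Classes of queries with a shared function were fixed from gene names, and the largest was the proteasome with 12 queries.

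The first comparison asked whether the arrays carry the mark that a cross leaves, the loss of strains linked to the query. With all arrays as deposited, strains altered within 25 genes of the query locus had a mean log2 ratio of -2.52 (SD 1.25 between 154 queries). The median was below 0 in 147 of 154 queries. Queries paired with other loci gave a mean of -0.03 (permutation p 1e-05, the smallest possible). The exceptions came from 17 arrays that showed a gain in place of the loss. With these turned the mean was -2.80 (SD 0.74), and all 154 queries were below 0, which for the other 7 the turning itself brings about. After turning, the loss was deepest next to the query, with a median of -4.91 at 1 to 5 genes, and had faded to -0.04 past 100 genes (up to 200). The query's own strain stood at -3.18 on 221 arrays. The turned arrays belonged to 13 queries, and 4 queries (DMA1, HRD1, UBC11 and UBP8) rested on them alone. Of 13 pairs of same-query arrays with 1 such array, 11 correlated negatively as deposited (median r -0.357 across strains). As deposited, 1724 of 48516 array pairs had an r below -0.3. After turning, 1318 of the same pairs did, and 953 of these held no turned array. The direction common to all arrays rests on linkage and is not settled by the labels.

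A second locus showed the opposite mark. On 57 arrays whose reference was a single deletion strain of the YEL068C gene, strains 1 to 5 genes from that gene had a median of 4.47 (3.15 to 6.38 per array). On 247 arrays with the mixed reference the same strains stood at 0.01. High values of strains there fell with the reference pool as a block in the fit. The YEL067C strain moved from 6.68 to 0.86 in the PRE9 query (adjusted p 0.103), HPA3 from 5.27 to 0.73 in ADD66 (0.131) and YEL068C from 2.17 to 0.51 in REX2 (0.451). SIT1 moved from 6.08 to 1.24 in NAS6 (adjusted p 0.0114) and from 3.57 (screens at 0.02 and 7.13) to 1.60 in POC4 (0.000244). These 2 calls passed in the blocked fit, but SIT1 lies in the same region. They are therefore not separated from the mark of the reference.

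**Figure D1:**
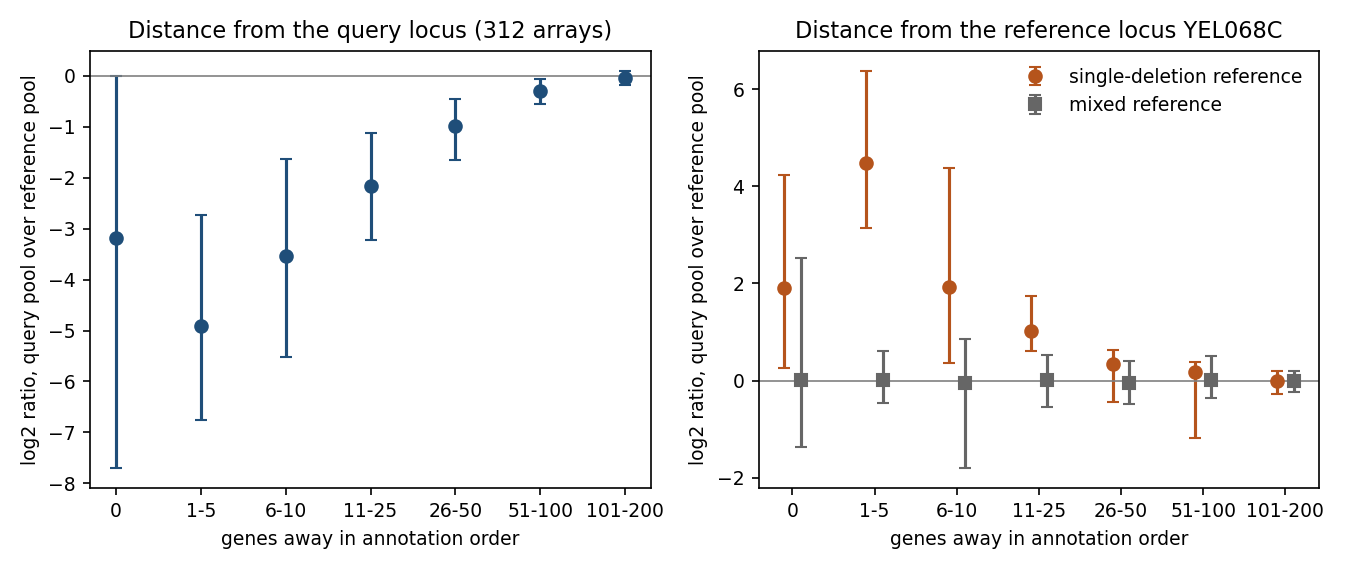
Median log2 ratio of strains (vertical axes) by distance in genes from the query locus (left, 312 arrays after turning, bars from the 5th to the 95th percentile of arrays) and from the YEL068C locus (right, bars from the lowest to the highest array). Strains 1 to 5 genes from the query stood at -4.91, and strains 1 to 5 genes from YEL068C stood at 4.47 on arrays with that single-deletion reference (circles) and at 0.01 on arrays with mixed references (squares).

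Screens of the same query resembled each other. Across strains outside the linked windows, 163 pairs of screens of the same query had a mean r of 0.445 (SD 0.272), and 154 of them were above 0. Screens of different queries had a mean r of 0.0571. The difference was 0.388 (permutation p 1e-05, the smallest possible), and 0.348 as deposited. Among 70 of 140 queries the mean r was at least 0.5, while it was below 0.2 in 32 and below 0 in 8. Part of the resemblance between queries went with a shared reference. Screens of different queries correlated at 0.180 where they shared a reference pool (1646 pairs) and at 0.0521 where they did not (40096 pairs). Only 2 same-query pairs shared a pool, so the agreement within queries did not rest on it (0.443 over 161 pairs of different pools).

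Across the 140 queries the question was how many strains rise or fall in level with each mutation. Of 547925 strain and query pairs, 12773 were lower and 6630 were higher, so 65.8% of the calls were lower. As deposited the counts were 11482 and 5799. With the reference pool as a block they were 11032 and 9054, and the lower share fell to 54.9%. Of these calls, 8817 lower and 3953 higher were shared with the first fit. The blocked fit also sets each query against the mean of its connected queries, so the fall cannot be assigned to pool adjustment alone. Lower calls appeared in 138 queries and higher calls in 139. The medians per query were 34.5 and 29. Calls were uneven: 20 queries held 53.1% of the lower ones. RPN4, the transcription factor of proteasome genes, had the most with 576 lower strains. UBP6, a proteasome-bound deubiquitinase, had 481, and the amino acid sensing regulator NPR3 had 472. Next came ADE4 with 415, the proteasome lid gene SEM1 with 408 and the RNA polymerase II phosphatase SSU72 with 374. Few strains were lower in SNR82, SAN1 and PCF11 (1 each), and RNQ1 and SPG5 were the queries without a lower call. DMA1 had 2 lower and 25 higher strains, but it rests on turned arrays alone, so these directions exchange as deposited. Higher calls were most frequent in RAT1, the nuclear exonuclease (299), GCN2 (246) and PTC1 (211).

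Some strains responded to many queries. The YBL081W strain was called in 36 of 137 queries, always higher. The ARL1 strain (Golgi traffic) was lower in 29 and higher in 6 queries, and the CDC36 strain (CCR4-NOT) was lower in 26 and higher in 8. The ESCRT strains VPS4, VPS24 and VPS60 were lower in 31, 30 and 24 queries and higher in 2, 3 and 9. The DOA1 strain (ubiquitin supply) was lower in 31 and higher in 2, the IRS4 strain in 26 and 7, and the PRE2 strain (20S core) in 22 and 11. The MMS2 strain (a ubiquitin-conjugating partner) was higher in 26 queries and lower in 7. In contrast, 1308 strains were not called in any query.

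Paralogs often compensate for each other, and the fixed paralog pairs tested this. The paralog strain was lower for 8 of 22 pairs, higher for 1 and not called for 13. Adjusted over the list alone, 9 pairs were lower and 1 was higher. The strongest loss was the RPS14B strain in the RPS14A query, at -7.12 ± 0.12 (adjusted p 3.47e-62). GSC2 in FKS1, the alternative glucan synthase subunits, stood at -6.81 ± 0.55 (adjusted p 3.1e-47). The mitotic cyclin strain CLB1 stood at -5.82 ± 0.51 in CLB2, and the ubiquitin-conjugating UBC4 strain at -5.57 ± 1.42 in UBC5. The elongation factor strain EFT1 was lower in EFT2 at -3.36 ± 2.41, with screens at -5.07 and -1.66. The nucleoporin strain ASM4 fell by 2.64 in NUP53, with an SD of 0.89. The TAX4 strain stood at -2.01 ± 0.03 in IRS4. The ubiquitin ligase strain DMA2 stood at -3.61 ± 0.66 in DMA1. That query rested on turned arrays alone and reads 3.61 as deposited, and UBC4 in UBC5 reads 1.01 as deposited.

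The exception in direction was the stress regulator MSN4, whose strain was higher in MSN2 at 2.12 ± 0.23 (adjusted p 3.17e-12). Pairs not called included RPL24A in RPL24B at -1.31 ± 0.03 (adjusted p 0.132), FPR4 in FPR3 at -0.86 ± 0.01 and the ribosome rescue strain SKI7 in HBS1 at -0.80 ± 0.11. RPL12A in RPL12B stood at -0.64 ± 0.02 and SLF1 in SRO9 at -0.57 ± 0.18. TAT1 in TAT2 stood at -1.06 with screens at -2.37 and 0.25, and the reverse cross, TAT2 in TAT1, at 0.82 ± 0.05. SHM1 in SHM2, ISW1 in ISW2, HTB1 in HTB2 and CAM1 in TEF4 lay between -0.07 and 0.15. PAP2 in TRF5 and RPS28A in RPS28B stood at 0.36 and 0.43. RPL9B in RPL9A was measured in 1 screen, at -3.19. Over 23 pairs the mean was -1.81 (SD 2.55, 17 below 0) against -0.09 for permuted pairs (permutation p 1e-05, the smallest possible). As deposited it was -1.17 (permutation p 3e-05).

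**Figure D2:**
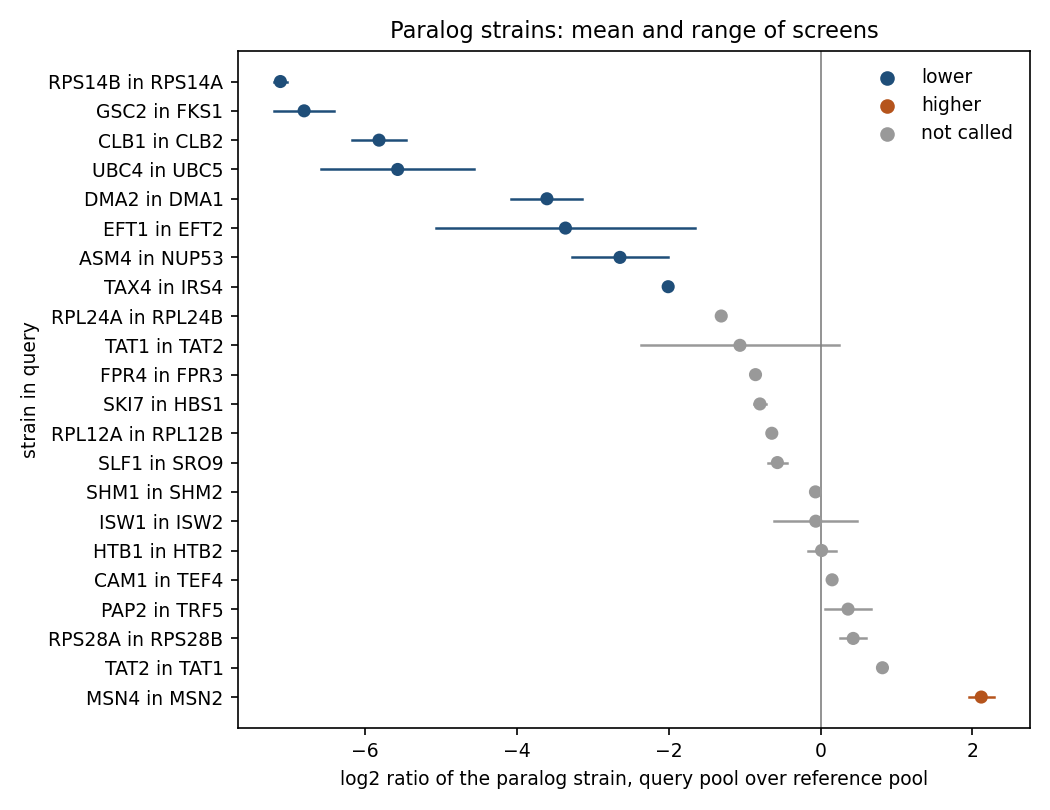
Mean log2 ratio of the paralog strain in its partner's query (horizontal axis), with bars from the lowest to the highest screen, for the 22 paralog pairs with at least 2 screens, coloured as lower, higher or not called. The 8 lower pairs lie between -7.12 and -2.01, and MSN4 in MSN2 is the 1 higher pair at 2.12.

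A further list held 19 tested pairs of genes in related pathways, of which 9 were lower, 3 were higher and 7 were not called. Adjusted over the list alone, 10 were lower and 3 higher. The UBP6 strain stood at -7.20 ± 1.2 in RPN4 (adjusted p 5.32e-21), and the RPN4 strain at -4.75 ± 0.43 in UBP6. The ubiquitin shuttle strain RAD23 stood at -6.99 ± 1.18 in RPN10, the query of a proteasomal ubiquitin receptor. CHS3, the chitin synthase strain, stood at -4.85 ± 0.33 in FKS1. The alpha-tubulin strain TUB3 stood at -3.04 ± 0.97 in the prefoldin query GIM4. MAK10, a partner of the N-terminal acetylase MAK3, stood at -2.77 ± 0.61 (3 screens) in that query. The RPN4 strain in PRE9 had a mean of -4.08 that rested on 1 screen (-7.86, against -0.31). The RRP6 strain in TRF5 stood at -1.69 ± 1.18, and at -0.30 (adjusted p 0.878) with the reference block. IRE1 in HRD1 stood at -1.10 ± 0.29, which is 1.10 as deposited.

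Higher calls were those of the PUF4 strain in RPL9A at 4.33 ± 1.44, of SWR1 in HTZ1 at 3.34 ± 1.26 and of TRM7 in TRM9 at 2.05 ± 0.52. PUF4 in RPL9A, and OCA1 and OCA2 with HCR1, were listed because the study is known to discuss them, so they are not independent evidence. OCA1 and OCA2 strains in HCR1 were not called (-0.29 ± 0.16 and -0.21 ± 0.00), nor was HCR1 in OCA2 (-1.90 ± 1.69, adjusted p 0.0956). SKI2 in NAM7 (-0.69), SAN1 in UBR1 (-0.73), RKR1 in VMS1 (-0.39, 4 screens) and PBP1 in LSM12 (0.27) were not called either. GET2 in GET3 (4.01) and SGS1 in RNH201 (-2.34) had 1 screen each. The mean over 21 pairs was -1.38 (SD 3.20) against -0.59 for permuted pairs (permutation p 0.0276). It was -1.27 as deposited (permutation p 0.0866) and -0.95 with the reference block (permutation p 0.0517), so the mean did not stay under 0.05.

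Query genes that act together were asked to have similar profiles. The 38 listed query pairs had a mean r of 0.316 (SD 0.261) across strains, against 0.0756 for other pairs, a difference of 0.240 (permutation p 1e-05, the smallest possible). Over screens with different reference pools the listed pairs had 0.202 and other pairs 0.0516. Among the listed pairs the highest r was that of OCA2 and OCA5, at 0.914. Over different pools it was 0.607, below the value of the next pair. The nonsense-mediated decay factors NAM7 and NMD2 stood at 0.80 (0.714 over different pools). The proteasome chaperones POC4 and IRC25 stood at 0.772 (0.469), the paralogs RPL37A and RPL37B at 0.734 (0.598), and the poly(A) nuclease subunits PAN2 and PAN3 at 0.698 (0.542). The box C/D proteins NOP1 and NOP56 stood at 0.599 (0.446). GCN2 and GCN4 stood at 0.427 (0.352). Some values went with a shared pool: REX2 and REX3 at 0.449 fell to -0.0251, CBF5 and SHQ1 at 0.424 to 0.0969, and NAS2 and NAS6 at 0.375 to 0.0619. RPS14A and RPS14B were at -0.126, RRP6 and TRF5 at -0.171, and PCF11 and SSU72 at -0.222.

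The proteasome class asked which strains depend on full proteasome function. Its 12 queries covered the core (PRE9), the regulatory particle (RPN10, SEM1), the transcription factor RPN4, the bound enzymes UBP6 and HUL5, and the assembly chaperones NAS2, NAS6, RPN14, ADD66, POC4 and IRC25. Compared with the other queries, 426 strains were lower and 64 higher. The total of 490 fell to 316 with the reference block (261 shared) and to 189 with quantile normalization. ADD66, IRC25, NAS2, NAS6, POC4, PRE9, RPN10 and RPN14 each had a screen against the same reference pool. Part of the total may go with that pool. The UBX2 strain, which lacks a recruiter of the Cdc48 unfoldase to the endoplasmic reticulum, ranked first by p, with a difference of -3.58 (class mean -3.61 ± 3.19, 11 of 12 queries below 0, adjusted p 4.49e-12). The endosomal strains DID2 (-2.18), VPS60 (-2.36) and SNX3 (-1.47) were lower, as were LTE1 (-1.33, mitotic exit), DCR2 (-1.26) and MRPL32 (-1.54, and -0.63 with the reference block, adjusted p 0.0245). The class's own genes were lower as strains: RPN4 at -3.57, SEM1 at -2.21, POC4 at -1.90, PRE9 at -1.68, NAS2 at -0.80 and ADD66 at -0.64. UBP6 at -1.53 had an adjusted p of 0.0549, and RPN14 (0.31), HUL5 (-0.29) and NAS6 (0.15) were below the size required. NAS2 stood at -0.46 (adjusted p 0.173) with the reference block, and the RPN4 strain could not be fitted with it.

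Of 39 measured strains of proteasome subunits and assembly factors, 31 were lower, 0 were higher and 8 did not pass (32 lower adjusted over the list alone, given below as "alone"). The Rpd3 and Set2 deacetylase pathway had 7 of 11 lower (7 alone), the mitochondrial ribosome 9 of 34 (9 alone) with 1 higher (2 alone), and ubiquitin delivery factors 4 of 10 (5 alone). Among deadenylation and decapping factors 4 of 10 were higher (4 alone) and 1 was lower (2 alone). Among single queries, the RPN13 strain, another ubiquitin receptor, stood at -6.56 ± 1.32 in RPN10 (adjusted p 5.31e-55), and TOF1, a replication fork factor, at -5.41 ± 0.11. The ceramide synthase strain LIP1 stood at -6.90 ± 0.46 in UBP6 and -5.94 ± 1.06 in RPN4. SAC6, an actin bundler, stood at -6.70 ± 0.73 in UBP6, and the translocation strain SEC66 at -5.92 ± 0.75 in PRE9. ADE1 stood at -4.60 ± 0.21 in SEM1, MTG1 at -3.45 ± 0.70 in POC4, and ROM2 at -2.67 ± 0.46 in IRC25. TAM41 in RPN4 was higher at 2.61 ± 0.93 and SGM1 in RPN14 at 2.81 ± 0.03. Some class shifts did not pass with the reference block. MLH3 (-0.64) moved to 0.08 (adjusted p 0.524), and FMP32, SPL2, TOS4 and YGL114W (0.63 to 0.69) stood at 0.05, 0.49, 0.46 and 0.38, under the size required.

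**Figure D3:**
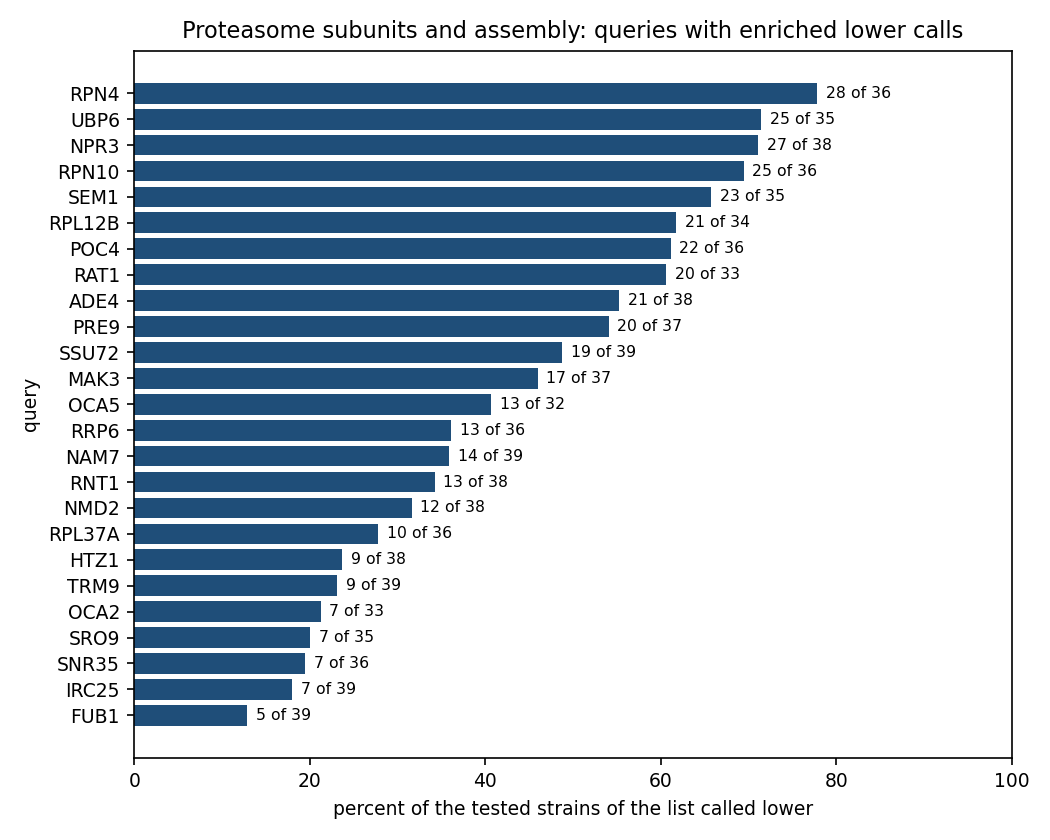
Percent of the measured strains of proteasome subunits and assembly factors (horizontal axis) that were lower in each of 25 queries enriched for such calls, with counts on the bars. RPN4 had 28 of 36 strains lower, and FUB1 had 5 of 39.

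The nuclear RNA processing class, with the exonucleases RAT1, REX2 and REX3, the RAT1 partner RAI1, the RNase III RNT1, the exosome nuclease RRP6, TRF5, SSU72 and PCF11, changed 131 strains relative to other queries. RRP6 itself was lower as a strain at -1.73 (6 of 7 queries below 0, adjusted p 6.93e-05), and SSU72 at -0.78 (adjusted p 0.0202). THP2, a THO transcription and export factor, was lower at -1.38, the chromatin protein NHP6B at -0.78, RPS29B at -1.46, MAK32 at -1.32 and YIL055C at -0.92 (class mean -0.96 ± 0.87). NHP6B and RPS29B were below 0 in only 5 of 9 queries, MAK32 in 7, and THP2 and YIL055C in 8. In single queries of the class, THP2 was called lower in 1, RPS29B in 2 and NHP6B in 3. THP2 could not be fitted with the reference block. DDR2 (-0.66) and LSP1 (-0.65) were lower. The FACT subunit POB3 was higher at 0.80, the repressor RFX1 at 0.99, HUA1 at 0.60 and NCE102 at 0.54. PCF11, REX2, REX3, RNT1, TRF5 and RAT1 as strains were not called, with differences between -0.35 and 0.13. With the reference block 308 strains passed, with quantile normalization 14, and without the first or the second replicate of each query 70 and 222. The 4 TETO2 queries, RAT1, RNT1, RRP6 and SSU72, are all in this class, so function and allele type are not separated for them. They shared reference pools with each other, but 102 of the 131 strains stayed with the reference block, among them YIL055C at -0.92 and RFX1 at 1.41, which argues against an additive pool effect as the whole source.

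Single queries of this class gave some of the strongest losses. The exosome cofactor strain MPP6 stood at -6.77 ± 1.85 in RRP6 (adjusted p 6.25e-63), and the THO strain MFT1 at -6.52 ± 1.33 in RRP6 and -4.46 ± 0.62 in SSU72. The ribosome assembly strain RPF2 stood at -6.13 ± 0.69 in TRF5 and the nucleolar NOP13 at -4.95 ± 0.46. The splicing strains ISY1 and BRR1 stood at -4.53 ± 0.19 and -3.35 ± 0.22 in REX3. The strains of RMD8 and RMD1 stood at -4.56 ± 1.37 and -3.63 ± 2.08 in RAI1, and RMD1 at -4.50 ± 0.24 in RNT1. YOS9 in RAT1 had screens at -9.62 and -2.86. SPT21 in RAT1 was higher at 5.50 ± 1.07, and IST3 in RAI1 at 3.36 ± 0.06. Of nuclear pore and export strains 5 of 20 were lower for the class (5 alone), of Rpd3 and Set2 strains 5 of 11 (5 alone), and of exosome and TRAMP strains 3 of 15 (4 alone).

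Ribosomal protein queries raised strains of the small subunit. Of 25 strains that differed from the other queries, 14 were lower and 11 higher. The total was 52 with the reference block (19 shared) and 45 with quantile normalization. RPS26B (1.08, class mean 1.04 ± 0.92, 8 of 10 queries not below 0), RPS7B (1.06), RPS27A (0.81) and RPS28A (0.97, adjusted p 0.0312) were higher, as was the processome strain BFR2 (0.75). Of 19 measured 40S strains, 5 were higher and 0 lower (13 higher adjusted over the list alone), and of 32 60S strains 0 passed under limma (10 higher alone). RPL24B (0.80, adjusted p 0.17) and RPS14B (-0.46, adjusted p 0.475) were not called. The Lsm ring strains LSM3 (-1.57) and LSM4 (-1.37), which act in mRNA decay and splicing, were lower, as were the helicase DED1 (-0.66), MTC2 (-0.66), BER1 (-0.94) and the phosphatase PTC6 (-1.47 against other queries, adjusted p 0.000279). LSM3 could not be fitted with the reference block. YPL077C (-0.56) stood at -0.44 (adjusted p 0.108) with the reference block. LSC1 (-0.85) rested on 1 query: the LSC1 strain stood at -5.68 ± 0.43 in RPS28B and was called in 1 of 135 queries. Without the first replicate of each query 0 class strains passed, and without the second 34.

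Within the class, RMD8 and RMD1 strains fell in both paralogs, to -5.28 ± 0.12 and -4.76 ± 0.47 in RPL37A and to -2.79 ± 0.21 and -2.52 ± 0.15 in RPL37B. LSG1, a GTPase of late 60S maturation, stood at -2.16 ± 0.20 in RPL24B. The RTT103 and APL2 strains stood at -2.90 ± 0.22 and -3.38 ± 0.66 in RPL9A. CHD1 stood at -3.55 ± 0.12 in RPL12B and -3.07 ± 0.49 in RPS14A. Higher strains were RPS18B in RPL37A (3.76 ± 0.83), NEW1 in RPL37B (2.23 ± 0.53), RPS28A in RPL24B (1.71 ± 0.09) and RPL17B in RPS28A (2.41 ± 0.15).

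**Figure D4:**
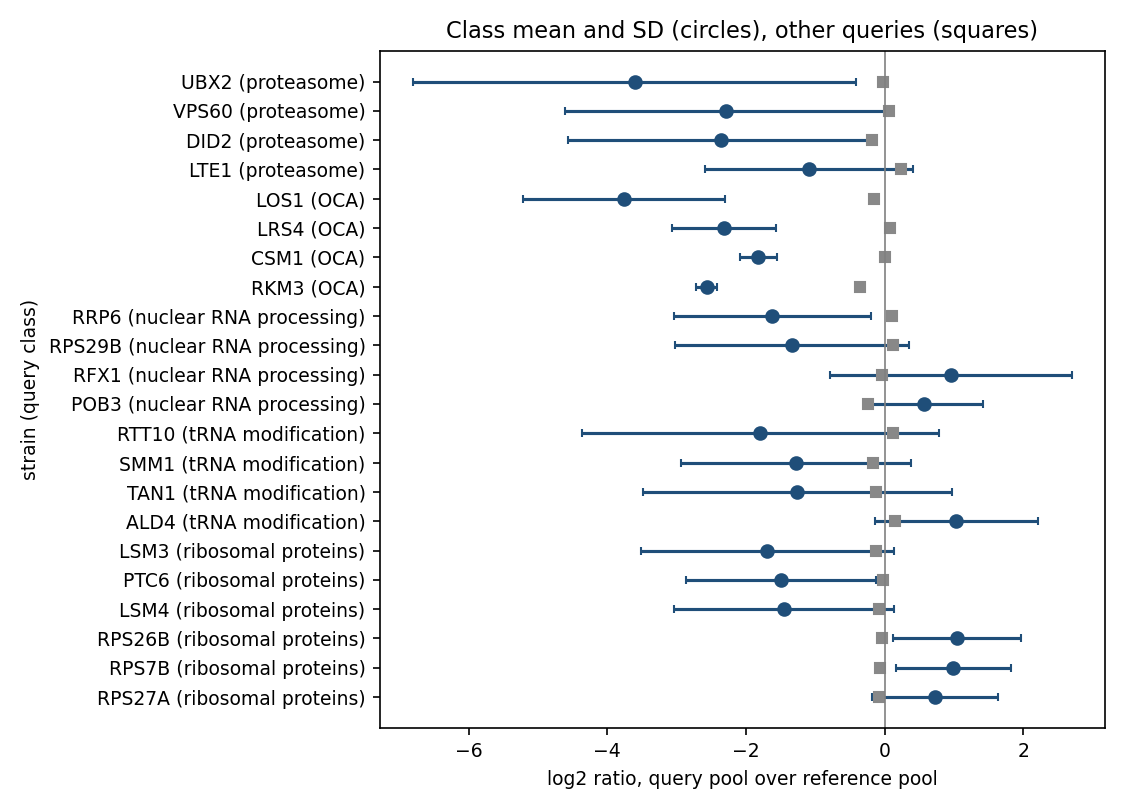
Class mean and SD between queries of log2 ratios (circles) beside the mean of all other queries (squares) for 22 strains of the class comparisons. UBX2 stands at -3.61 in proteasome queries and -0.03 elsewhere, and LOS1 at -3.76 in OCA queries and -0.16 elsewhere.

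Queries in tRNA modification changed other tRNA modification strains. RTT10, a partner in tRNA methylation at the wobble base, was lower at -1.91 (class mean -1.79 ± 2.58, 4 of 6 queries below 0, adjusted p 4.81e-06). SMM1, a dihydrouridine synthase, was lower at -1.10, TAN1, needed for cytidine acetylation, at -1.14, and TRM82, a methyltransferase subunit, at -0.68. BCK2 (-1.16, not fitted with the reference block) was lower and ALD4 (0.88) was the 1 higher strain of 8. Without the second replicate of each query 2 class strains passed, and the share of random classes as large was 0.0733 after correction over classes. LHP1 (-0.69) and YTH1 (-0.60) had adjusted p values of 0.101 and 0.166 with the reference block. Of 21 strains of other tRNA modification enzymes 4 were lower (10 alone). TRM1, RIT1, TRM112, TRM11 and PUS1 as strains were not called. In single queries TAN1 stood at -5.71 ± 0.36 and RTT10 at -4.15 ± 0.28 in TRM1, the dimethylguanosine enzyme. RTT10 stood at -4.67 ± 2.95 in TRM11. In the pseudouridine synthase query PUS1, TRM8 stood at -3.59 ± 2.09 (4 screens) and TRM10 at -3.78 ± 2.58 (3 screens), with each screen below -1. GCD6, a subunit of the initiation factor eIF2B, stood at -4.19 ± 0.05 in RIT1, which modifies initiator tRNA. PEX14 and PEX10, peroxisome import factors, stood at -4.16 ± 1.32 and -3.74 ± 0.40 in MOD5. PRE9 was higher in PUS1 at 1.98 ± 0.62 (4 screens), and IES3 in TRM9 at 3.63 ± 0.20.

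The OCA class joined 4 genes, OCA1, OCA2, OCA5 and OCA6. Chance could not be excluded for its total of 13 strains, as 14 of 100 classes (the other 99 random) had as many, up to 181. LOS1, a tRNA export receptor, was lower at -3.60 (class mean -3.76 ± 1.45, 4 of 4 below 0, adjusted p 8.27e-06). The nucleolar and monopolin strains LRS4 (-2.41) and CSM1 (-1.83) fell together. RKM3, a ribosomal protein methyltransferase, was lower at -2.21, YDR042C at -3.52, GAL10 at -2.54, PRS5 at -0.90 and DDP1, an inositol pyrophosphate phosphatase, at -0.62. Of the total 12 were lower and 1 was higher, SSO2 at 0.83 (adjusted p 0.183 with the reference block). The total was 20 with the block and 28 with quantile normalization. OCA6 (-1.41, adjusted p 0.132), OCA2 (-1.67), OCA1 (-0.97) and OCA5 (-0.72) as strains were not called, and of 8 OCA list strains 1 was lower (4 alone). With the reference block OCA6 passed, at -1.69 (adjusted p 0.0468). Without the first replicate of each query 4 class strains passed, and without the second 85. CSR2 stood at -3.15 ± 1.57 in OCA1, VAC14 at -2.40 ± 0.88 in OCA2, LIP1 at -2.89 ± 1.66 in OCA5 and GGA1 at -2.35 ± 0.92 in OCA6.

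The mRNA decay class had 4 strains past the threshold, all lower, a total for which chance could not be excluded (34 of 100 classes had as many). It was 7 with the reference block and 19 with quantile normalization. YOR072W stood at -2.28 (class mean -2.21 ± 1.12, 4 of 4 below 0, adjusted p 1.28e-05). NAB3, a nuclear termination factor, stood at -1.16 (adjusted p 0.0678 with the reference block), TUB3 at -2.06 and NDD1 at -0.53. NAB3 and TUB3 were each below 0 in 2 of 4 queries, and NDD1 in 4 of 4. The fall of TUB3 came from the poly(A) nuclease queries: it stood at -5.24 ± 1.32 in PAN2 and -4.48 ± 0.06 in PAN3. The tubulin cofactor strain CIN1 stood at -3.46 ± 0.62 in PAN2. Of 8 prefoldin and tubulin folding strains, 6 were lower in PAN2 (6 alone; enrichment adjusted p 3.1e-08) and 4 of 7 in PAN3 (4 alone; 6.58e-06). In the decay factor NAM7 (also UPF1) the LIP1 strain stood at -5.04 ± 0.04 and SEY1, which fuses endoplasmic reticulum tubules, at -3.78 ± 0.07. With the reference block these were -3.82 (adjusted p 3.44e-05) and -1.43 (0.00796). Both NAM7 screens had the same reference pool, in which SEY1 had a median of -3.71 over 10 screens, against 0.06 over 288 others. SIW14 stood at -2.45 ± 0.77 in NMD2. PAN2, NMD2, PAN3 and NAM7 as strains were not called.

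Queries of snoRNP proteins gave 44 lower and 23 higher strains, and snoRNA queries 44 and 24, yet most of these went with the reference pool. NOP58, a box C/D protein, was higher for snoRNP queries at 0.90 (5 of 5 not below 0, adjusted p 1.96e-05) and stayed past the threshold with the reference block (0.86, adjusted p 0.000985). The other class strains named by the rule did not: RAD28 moved from -0.88 to -0.34, YBR138C from -0.99 to -0.20, DAS2 from -1.08 to -0.19, DIT1 from -0.91 to -0.19, FIR1 from -0.71 to -0.46, ANT1 from -0.70 to -0.37, RIM2 from -0.59 to -0.28 and PMT5 from -0.55 to -0.27. EDC2, SAM4 and ETP1 moved from 0.55, 0.58 and 0.58 to 0.13, 0.12 and 0.26. Only 3 of the 67 strains were shared with the blocked fit, and 8 of the 68 for snoRNAs. Without the first or the second replicate these counts were 27 and 191, and 8 and 314. CBF5, NHP2, SHQ1 and NOP56 as strains were not called.

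Single snoRNP queries gave partners on the same side in every screen, which the naming rule requires. RPB10, a subunit shared by RNA polymerases, stood at -3.31 ± 0.27 in the pseudouridine synthase query CBF5 (adjusted p 2.73e-30). The CBF5 screens correlated at only 0.0089 across strains, so this small SD does not stand for the whole profile. PUF4 stood at -3.37 ± 1.11 and CIS1 at -3.06 ± 0.27 in NOP1. TRM112, a methyltransferase activator, was higher at 3.10 ± 0.53 in NOP1 and 3.31 ± 0.32 in NOP56. For snoRNA queries, YBR138C (-1.03), DAS2 (-0.90), GCD14 (-0.58), SHM1 (-0.64) and YDR124W (-0.67) stood between -0.22 and -0.05 with the reference block. YML018C (-0.65) and ALD5 (-0.61) stood at -0.29 and -0.31, and BIT2 (-0.55) at -0.47. URN1 (0.62), TOA1 (1.2) and RNP1 (0.76) stood at -0.09, -0.01 and 0.35, while YCL049C (0.52) stayed at 0.53 (adjusted p 0.000218). In single queries, SWI5 stood at -2.17 ± 0.30 and ADP1 at 2.76 ± 0.56 in SNR49.

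Ubiquitin and SUMO queries had 1 class strain, UBP5 at -0.60 (class mean -0.55 ± 0.50, 10 of 10 below 0, adjusted p 0.0218), which reads 0.09 as deposited. It did not pass without the first or the second replicate or without the turned arrays, and could not be fitted with the reference block. Chance could not be excluded for this total (27 of 100). In the ligase query TOM1, the ADD37 strain stood at -6.72 ± 0.19 and AVL9, a secretory factor, at -6.69 ± 0.25, while RPS25A was higher at 3.53 ± 0.13. In VMS1, a factor of ribosome-associated quality control, the helicase strain HCS1 stood at -6.10 ± 1.68 and GCN20 at -1.95 ± 0.36 (4 screens each, 1 of them turned), and as deposited at -4.11 and -1.13. VMS1 also lowered SKI2, SKI3, SKI7 and SKI8, 4 of 7 strains of the SKI and ribosome rescue list (4 alone; enrichment adjusted p 1.47e-06, and 4 lower as deposited). The SUMO ligase strain NFI1 stood at -2.31 ± 0.52 and the nuclease SLX1 at -1.05 ± 0.10 in the SUMO query SMT3, whose screens correlated at -0.121. HAC1, the unfolded protein regulator, stood at -1.37 ± 0.20 in HRD1 and reads 1.37 as deposited. In HRD1 3 of 13 strains of the degradation and unfolded protein list were lower (3 alone), HAC1, IRE1 and LHS1, and 0 as deposited. The polymerase III repressor strain MAF1 stood at -2.99 ± 0.00 in UBR1.

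Chromatin queries had 0 class strains under limma, with 114 at an unadjusted p under 0.05. The variant histone query HTZ1 had the most lower strains of them, 249. CIN1 stood at -5.35 ± 1.60 and PAC2, both tubulin cofactors, at -4.56 ± 0.46 in HTZ1. There, 6 of 6 prefoldin and tubulin strains (6 alone) and 9 of 11 Rpd3 and Set2 strains (9 alone) were lower. In the deacetylase query HDA1, 7 of 10 Rpd3 and Set2 strains were lower (8 alone; enrichment adjusted p 1.38e-09), among them RCO1, EAF3 and SET2. RIM11 stood at -2.90 ± 0.05 in NAP1, and RRT2 at -3.93 ± 1.21 in RCO1. SNC2 and ROM2 stood at -2.88 ± 0.33 and -2.88 ± 0.74 in UBP8, both 2.88 as deposited. VPS75 was higher in PHO23 at 2.03 ± 0.04. HTB2, NAP1, RCO1, ESC1, UBP8, HDA1, PHO23 and ISW2 as strains were not called.

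Translation queries also had 0 class strains under limma, with 314 at an unadjusted p under 0.05. RLI1, the ribosome recycling factor, stood at -7.44 ± 0.01 in HCR1, a query of initiation factor eIF3 (adjusted p 2.66e-60). In HCR1, 5 of 7 SKI and ribosome rescue strains were lower (5 alone), HBS1 and SKI2, SKI3, SKI7 and SKI8. MYO5 stood at -2.64 ± 0.07 there and SRP40 at 3.09 ± 0.17. In GCN2, the kinase of amino acid starvation, the tryptophan permease strain TAT2 stood at -5.49 ± 0.21 and ERG5 at -4.55 ± 1.81. The septin strain SHS1 stood at -4.19 ± 1.01 and the nucleoporin NUP2 at -3.74 ± 0.82 in the RNA-binding query SRO9. The spindle checkpoint strains MAD2 and MAD1 stood at -2.15 ± 1.69 and -2.11 ± 1.61 in HBS1, where 1 screen is turned, and at -1.19 (adjusted p 0.0791) and -1.14 (0.015) as deposited. SRO9, EFT2, GCN4, SLH1, TEF4, HBS1 and HCR1 as strains were not called.

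Whole lists were also compared with the classes, and 6 of 319 class and list pairs passed. Proteasome queries lowered the proteasome list to a mean of medians of -1.44 (SD 1.53, 10 of 12 queries below 0, permutation adjusted p 0.00319) and ubiquitin delivery to -0.69 (SD 0.82, permutation adjusted p 0.00798). Their Rpd3 and Set2 value was -1.23 (permutation adjusted p 0.0415, and 0.0562 with the reference block). Meiosis and sporulation strains stood at 0.07 (0.0415, and 0.0596 with the block). Ribosomal protein queries raised 40S strains to 0.76 (SD 0.97, permutation adjusted p 0.0191). Queries in tRNA modification lowered other tRNA modification strains to -0.25 (SD 0.36, permutation adjusted p 0.0484). This value was 0.0521 with each strain centred, as for Rpd3 and Set2 and for meiosis, and 0.0516 without strains linked to the reference deletion.

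Per query, 149 of 4109 query and list pairs were enriched for lower calls, in 71 queries, and 92 of these stayed among 113 with the reference block and 123 among 130 as deposited. The proteasome list was enriched in 25 queries, Rpd3 and Set2 in 21, 60S proteins in 11 and SKI in 10. Strains of these lists were lower in many queries: in 8.51%, 11.3%, 4.07% and 8.63% of their tested pairs. Over all strains 12773 of 547925 pairs were lower. The Fisher tests take every strain as equally likely to be called, so they do not separate a property of the query from strains that respond often. Outside the proteasome class, 27 of 38 proteasome strains were lower in NPR3 (27 alone; adjusted p 2.46e-14), 20 of 33 in RAT1 (20 alone) and 21 of 34 in RPL12B (22 alone). In FUB1, a proteasome-bound protein, 5 of its 6 lower strains were proteasomal: POC4, PRE2, PRE5, PRE7 and PUP2 (5 of 39 on the list, 5 alone; adjusted p 8.19e-08). The FUB1 screens correlated at -0.207, the lowest value of any query, and POC4 stood at -4.02 ± 2.85, so these calls rest on screens that did not match. MAF1 lowered 9 of 20 tRNA modification strains (9 alone; adjusted p 7.98e-10), among them TRM1, TRM8, TRM82 and TAN1. The MAF1 screens correlated at only 0.1465. The karyopherin query SXM1 lowered 13 of 31 60S strains (13 alone; adjusted p 8.44e-08). YLR177W and OTU1 each lowered 9 60S strains (10 alone each), RPL11B and RPL16A among them, and for OTU1 the adjusted p was 0.154 with the reference block. RRP6 lowered 13 of 25 ribosome assembly strains (14 alone), NOP2, NOP4 and EBP2 among them. FKS1 and PTC1 lowered 11 of 17 and 10 of 15 cell wall strains (11 alone each), with BCK1, BNI4, CHS3 and SKT5 in both. OCA strains were lower in NMD2 (6 of 8, 6 alone) and in NAM7 (6 of 8, 6 alone), where the adjusted p was 0.885 with the block. Lists for drug resistance, meiosis, osmotic signalling and translation initiation were enriched in 0 queries (one-sided Fisher exact tests), and mating in 1, PBS2, with FUS1 and FUS2 (adjusted p 0.043, 0.0625 with the block). Of the V-ATPase list 1 strain was measured, so this list was in effect not tested.

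Paralogous ribosomal protein queries were compared directly. Some endosomal sorting strains were low in RPS14A and high in RPS14B: VPS20 stood at -3.53 against 2.71 (difference -6.24, adjusted p 2.22e-06), VPS25 at -4.05 against 1.87, SNF7 at -3.42 against 2.58 and SNF8 at -3.47 against 2.26. The splicing strain MUD2 stood at -2.70 against 1.75 (adjusted p 3.81e-09). The endosomal strains were grouped after their values were seen, with no list and no enrichment test, and other strains of this pathway were low in many queries (VPS4 in 31, VPS24 in 30). In all 90 strains were lower and 8 higher in RPS14A, and the total of 98 rose to 192 with the reference block. RPS28A and RPS28B differed in 13 strains, with YKT6, a membrane fusion factor, at 2.45 against -0.57 and LSM3 at -2.32 against -0.11, and in 2 with the reference block. RPL37A and RPL37B differed in 6 (30 with the block), all 6 lower in RPL37A, with YGR054W at -3.63 against -0.68 and PUB1 at -3.18 against -0.32. Leaving out the first or the second replicate gave 2 and 46 strains for RPS14, 0 and 9 for RPS28, and 0 and 1 for RPL37.

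The number of lower calls was compared between allele types, and no difference was detected between deletions and the others pooled. The 126 deletion queries had a median of 33.5 lower strains and the 14 DAMP and TETO2 queries had 39.0 (permutation p 0.916), with a range of 1 to 374 among the latter, from PCF11 to SSU72. As deposited the difference of medians was -6.0, against -5.5. The pooled group is mixed: the 4 TETO2 queries had 249 to 374 lower strains (RNT1, RAT1 with 292, RRP6 with 370 and SSU72) and each of the 10 DAMP queries had fewer, from PCF11 up to TRM112 with 60 and then NOP56. This split was seen after the comparison and was not tested.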

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

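The direct comparisons of paralogous ribosomal protein queries were planned, and the endosomal strains were grouped after their values were seen. RPS14A and RPS14B drew attention because the difference itself passed a test for 98 strains (2 screens each), with the endosomal strains VPS20, VPS25, VPS36, SNF7 and SNF8 low in RPS14A and high in RPS14B. RPS28A and RPS28B differed in 13 strains by the same test, and RPL37A and RPL37B in 6. No explanation was tested for these 3 results, and the screens per query are few.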

How the results depend on the processing

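The alternatives that leave all arrays as deposited, leave out the 17 turned arrays, leave out strains linked to the reference deletion or ask every screen to pass 1 were chosen after the data were seen. So was the reference block for lists and allele type. Of 260 comparisons of 24 results with an alternative, 175 kept their direction and their side of the threshold or stayed within 1.5 times the count, 79 moved further, 4 no longer passed and 2 reversed. Linkage (-3.89 to -1.78), agreement between screens (0.295 to 0.528), paralog pairs (-1.96 to -1.17), query pair similarity (0.183 to 0.265) and the number of enriched lists (113 to 150) kept direction and side under every alternative run. Where no cause is given below, the cause was not tested.

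Counts of interactions lower (12773) and interactions higher (6630) moved where fewer screens or strains were tested or the size changed by construction. Leaving out a replicate gave 7661 to 8573 lower and 3364 to 3431 higher. Queries left with 1 screen were then assumed to vary like the others. Strains on every array gave 5368 and 2498. With linked strains kept, 19647 were lower. A size of 0.5 gave 10536 higher, a size of 2 gave 6203 and 1080, and every screen past 1 gave 3750 higher. Quantile normalization gave 10213 and 5863. Without centring the counts were 11974 and 7787, as array medians up to 0.48 then stay in the values. The related pairs (-1.38) were at -0.95 with the reference block, -1.27 as deposited, -1.40 without the turned arrays and -1.10 without strains linked to the reference deletion, and none of these 4 passed 0.05.

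For the classes, the reference block moved the proteasome count from 490 to 316, snoRNP proteins from 67 to 18, ribosomal proteins from 25 to 52, OCA from 13 to 20, nuclear RNA processing from 131 to 308, mRNA decay from 4 to 7, ubiquitin and SUMO from 1 to 0 and translation from 0 to 2. The 1 ubiquitin and SUMO strain, UBP5, could not be fitted with the block, so its call was not tested there. The snoRNA count went from 68 to 84 with 8 strains shared. Quantile normalization gave 189 for the proteasome, 39 for snoRNP proteins, 45 for ribosomal proteins, 28 for OCA, 14 for nuclear RNA processing, 19 for mRNA decay, 4 for ubiquitin and SUMO and 5 for translation. No centring gave 3 for translation. With fewer strains tested, those on every array, the counts were 183 for the proteasome, 27 for snoRNP proteins, 22 for snoRNAs, 4 for ribosomal proteins, 4 for tRNA modification, 2 for OCA, 55 for nuclear RNA processing, 1 for mRNA decay, 0 for ubiquitin and SUMO and 2 for translation.

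Leaving out each replicate in turn gave 411 to 451 for the proteasome, 27 to 191 for snoRNP proteins, 8 to 314 for snoRNAs, 0 to 34 for ribosomal proteins, 2 to 8 for tRNA modification, 4 to 85 for OCA, 70 to 222 for nuclear RNA processing, 3 to 5 for mRNA decay, 0 to 0 for ubiquitin and SUMO and 0 to 1 for translation. The lower end came without replicate 1, except for tRNA modification and mRNA decay, where it came without replicate 2. A difference of 0.3 gave 829 for the proteasome, 190 for snoRNP proteins, 255 for snoRNAs, 13 for tRNA modification and 215 for nuclear RNA processing. A difference of 1 gave 229 for the proteasome, 15 for snoRNP proteins, 7 for snoRNAs, 9 for ribosomal proteins, 4 for tRNA modification, 53 for nuclear RNA processing and 0 for ubiquitin and SUMO. As deposited the counts were 443 for the proteasome, 69 for snoRNP proteins, 71 for snoRNAs, 34 for ribosomal proteins, 9 for tRNA modification, 13 for OCA, 116 for nuclear RNA processing, 4 for mRNA decay, 3 for ubiquitin and SUMO and 2 for translation. Without the turned arrays ubiquitin and SUMO had 0 and translation 6. Chromatin stayed at 0 under each of these settings.

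With each strain centred on its median, 3 class and list pairs passed in place of 6, and 5 passed as deposited. With the reference block 7 passed: Rpd3 and Set2 and meiosis were lost for the proteasome, while nonsense-mediated decay for snoRNP proteins (permutation adjusted p 0.0436) and, for nuclear RNA processing, ribosome assembly (0.0483) and the exosome and TRAMP list (0.0185) were gained. With list means 7 passed, the exosome and TRAMP list among them (0.00319), without Rpd3 and Set2 (0.0617) and meiosis (0.356). RPS28A and RPS28B (13 strains) differed in 2 with the reference block, 26 with quantile normalization, 6 among strains on every array and 0 to 9 without a replicate. RPS14A and RPS14B (98) differed in 192 with the block, 37 on every array and 2 to 46 without a replicate. RPL37A and RPL37B (6) differed in 30 with the block, 3 on every array and 0 to 1 without a replicate. As deposited these 3 counts were 12, 78 and 5. The allele type difference of -5.5 reversed to 1.5 at a size of 2 (permutation p 0.550) and to 3.0 with the reference block (permutation p 0.619).

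The replicate numbers were checked as a pairing, on the deviation of each screen from the mean of its query. Over 138 queries, deviations with the same number had a mean r of 0.019. The mean of -0.019 for different numbers mirrors this value by construction, as the paired deviations of a query are opposites. The mean was small, but 237 of 276 screens had their best match among screens of their own number. Best matches are mirrored in the same way, so the 276 screens are not independent here. No chance level was computed for this count. Screens of the same number may share some structure. Some reference pools held screens of a single number only, so number and pool were not separated. The labels give only the numbers, so they were not taken as pairs. With replicate number as a block, 12546 pairs were lower and 6206 higher, of which 11671 and 5463 were shared with the fit without it.

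Of the named strains, the reference block kept 276 of 367, weakened 83, strengthened 2 and reversed 6. The reversed ones were MLH3 in proteasome queries (0.083), URN1 (-0.089) and TOA1 (-0.0071) in snoRNA queries, MRPL32 in ADD66 (0.10), SYP1 in HUL5 (0.21) and ACC1 in SNR82 (0.060). With all arrays as deposited, 374 of 408 stayed, 17 weakened and 17 reversed, each in a query with turned arrays or a class holding one. These were UBP5 in ubiquitin and SUMO queries (0.092), SNC2 in UBP8 (2.88), ROM2 in UBP8 (2.88), NPA3 in UBP8 (-1.44), EDC1 in UBC11 (1.14), SBA1 in UBC11 (1.12), NAS2 in UBC11 (-1.41), HAC1 in HRD1 (1.37), SIP3 in HRD1 (1.26), FKS1 in HRD1 (-1.64), IRE1 in HRD1 (1.10), DMA2 in DMA1 (3.61), ESC2 in DMA1 (1.86), NBP2 in DMA1 (-2.51), SGO1 in HBS1 (-0.71), YIR043C in SLH1 (0.0054) and UBC4 in UBC5 (1.01). Quantile normalization kept 385 of 408, no centring 403 and strains on every array 141 of 142. Without replicate 1, 186 weakened, and without replicate 2, 143, with fewer screens. The deposited ratios carry no background values, so limits set by signal over background could not be assessed.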

Other observations

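Chosen after the results were seen were the tests of the reference locus by linkage, of the NPR3 and UBP6 profiles, of adjacent genes at DSE3 and PNT1, and of random classes. The gene pairs of the next paragraph were also chosen after their values were seen, apart from those of queries with most calls.

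The following pairs in queries outside the classes were picked by known function, without a test of a shared theme. In RAD50, a recombination query, the RNase H2 strains RNH201, RNH202 and RNH203 stood at -3.05 ± 0.33, -3.15 ± 0.29 and -3.0 ± 0.13 (2 screens each). In the RNH201 query the recombination strains RAD59, MUS81 and MMS4 stood at -2.06 ± 0.11, -1.49 ± 0.35 and -1.46 ± 0.96. These rest on 1 turned screen: as deposited they were -0.08, -0.25 and -0.68 and not called. In the tryptophan permease query TAT2, the tryptophan synthase strain TRP5 stood at -7.55 ± 0.50, and GCN20, GCN3 and GCN4 of the amino acid control pathway at -4.14 ± 1.34, -3.76 ± 0.48 and -3.58 ± 0.49. In TAT1, the leucine regulator strain LEU3 stood at -5.20 ± 0.88. NAM8 and MUD1 both belong to the U1 splicing particle, and the MUD1 strain stood at -6.06 ± 0.77 in NAM8. The phosphatase strain PTP2 stood at -5.61 ± 0.57 in PTC1, another phosphatase of osmotic signalling, where PRE9 was higher at 4.70 ± 1.51. MIS1, a mitochondrial folate enzyme, had screens that spread widely in SHM2 (-3.96 ± 2.91).

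Queries with many calls had clear partners too. In FKS1 the bud neck strain BNI4 stood at -6.19 ± 0.21, and in IRS4 the vesicle strain SNC2 at -5.02 ± 0.71. In MAK3 both fork protection strains fell, TOF1 to -5.99 ± 0.61 and CSM3 to -5.79 ± 0.72 (3 screens). In SXM1 the adenine strains ADE1 and ADE6 stood at -5.78 ± 0.76 and -5.19 ± 1.42 (3 screens), and SPT8 at 3.43 ± 1.38 (4 screens). In ADE4 the FIG2 strain stood at -6.11 ± 1.85, in CAJ1 FOX2 at -5.58 ± 1.52, and in PIN4 HOG1 at 2.78 ± 0.56. Among queries with 1 screen and no test, the lowest strain was SAC6 in CAP1 (-7.38), RSA3 in YCR016W (-6.12), RMD8 in SNR67 (-8.52), SHC1 in YIL096C (-4.36), RPL33A in FPR4 (-3.40) and SEY1 in AIR2 (-3.49), where AIR1 came next (-2.86). SEY1 was also lowest in EDC2 (-3.69) and PBY1 (-3.71), and these 3 screens shared a reference pool. Some strains followed a single reference pool. SEY1 had a median of -3.71 in 10 screens of that pool and 0.06 in 288 others. In another pool YBR138C had -2.83 in 13 screens and -0.10 in 288 others, and in a further pool HSP12 had -3.39 in 14 and 0.00 in 286.

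Strains beside YEL068C were high on arrays with the single-deletion reference, with a median of 4.47 at 1 to 5 genes on 57 arrays, as linkage to a marked reference deletion would give. An interaction of the query genes with that region was argued against: in 44 queries screened against both kinds of reference, the same strains had a median of 4.42 (2.29 to 6.38) on the single reference and 0.0194 (-0.46 to 0.56) over 47 screens with mixed references. Linkage in the reference remains the candidate explanation.

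NPR3 and UBP6 act in amino acid signalling and at the proteasome, yet their profiles correlated at 0.893 across strains, beside 0.856 and 0.962 for screens of either query, and they shared 354 of 472 and 481 lower strains where 53.7 would overlap by chance. A shared reference pool cannot be the source by design, since NPR3 and UBP6 had no pool in common. The lowest r between their screens was 0.8135. A swapped strain was argued against by linkage: strains near UBP6 stood at -0.10 in NPR3 and those near NPR3 at -0.172 in UBP6, against -2.02 and -3.42 for their own loci. After centring each strain on its median over queries, r was 0.890, which argues against an offset of strains common to all queries. Centring on a median cannot remove a sensitivity of strains that shows only in some queries, so that is not addressed. The pair was not singular: SEM1 and UBP6 correlated at 0.841 (0.812 over different pools), RPL12B and UBP6 at 0.835 (0.778) and ADE4 and NPR3 at 0.828 (0.698). A response shared by several such queries may explain the resemblance, and no biological explanation was tested.

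The neighbouring DSE3 and PNT1 strains stood at -4.82 ± 0.31 and -4.29 ± 1.17 in GIM4, a prefoldin query, and 34 other strains within 25 genes had a median of -0.0044 (-1.90 to 3.08), which argues against a second marked locus. The RBL2 gene of tubulin folding, whose strain was not measured, lies between them in the R64 gene order, and these deletions may affect it. Neighbours were first compared over all queries. Strains 2 genes apart, as these are, shared 3.92% of lower calls, within the 2.76% to 3.97% seen at 10 to 40 genes, while directly adjacent strains shared 4.47%. On the pair itself, r over the other queries was 0.310, against a 95th percentile of 0.324 among 78231 pairs 10 to 40 genes apart, and 5.62% of these were as high. An effect on the adjacent gene is left open by this value, and r over all queries (0.795) and the values in HTZ1 (-0.89 and -1.46) had been seen before the test.

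Random classes of the same size were drawn 99 times for each class, freely from all tested queries. The share of draws as large was under 0.05 for 6 of 11 classes, and for 5 after correction over the 11 classes. A small share speaks only against a free draw of queries. The proteasome had 490 strains (highest other 59), nuclear RNA processing 131 (11), snoRNAs 68 (5) and ribosomal proteins 25 (13), each with 1 of 100 as large, the real one included. For snoRNP proteins (67) 2 of 100 were as large, the highest with 161, and for tRNA modification (8) 4 of 100, the highest with 13 (adjusted shares 0.044 and 0.0733). Chance could not be excluded for OCA (13; 14 of 100, highest 181), mRNA decay (4; 34 of 100, highest 462) and ubiquitin and SUMO (1; 27 of 100, highest 38). Chromatin and translation had 0 strains, so all 100 of 100 were as large by construction (highest 21 and 128), and the draws tested nothing there. Random classes with several times the real count point to a structure of the queries beyond the classes. The draws did not keep the reference pools of a class, so they do not exclude an effect of shared pools. These pools are a candidate source for the snoRNA and snoRNP classes, where 84 and 18 strains passed with the reference block and 8 and 3 were shared. They are not excluded for part of the proteasome total either, as most proteasome queries had a screen against the same pool.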
